A study of Mus musculus with 10 samples.

How the data were processed

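The series measured the RNA of 10 single leptin receptor reporter neurons from the mouse nucleus of the solitary tract, 5 of each of 2 firing types, with 1 library per neuron. The labels give the molecule as total RNA and the libraries as made by standard Illumina protocols. Per the submitters' processing notes, cutadapt 1.13, STAR (version not stated), HTSeq 0.6.1p1 and DESeq2 (version not stated) were used with the mm10 build. The order of the steps, the annotation release, the strand option and any cDNA amplification are not given in the sources used here. The deposited values are whole-number counts of reads per gene, per the file headers and the values themselves, with no normalization and no molecular identifiers. Each table listed the same 25006 Ensembl gene identifiers and no rows for unassigned reads. Counts were 0 in all 10 neurons for 10399 genes, which left 14607. The 13 mitochondrially encoded genes listed had 0 counts in total, so the share of mitochondrial reads, a usual sign of cell quality, could not be examined.

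Symbols were matched by identifier for 24942 genes, and GENCODE M21 coordinates on GRCm38, the assembly that mm10 names, for 24991. Of the 81 named genes, 6 share exon bases with another gene that has counts (Kcnma1, Nefl, Cnp, Csf1r, Ndufa2 and Gnas, in each case a gene on the opposite strand), and their values are uncertain because the strand option is not known. None of the 20 genes with the largest differences does. Near-identical copies can share reads with ribosomal protein genes such as Rpl22 and Rps13.

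CPM was computed from the deposited counts as counts divided by the library's summed gene counts on the usual CPM scale, and levels are log2(CPM + 1). By sequencing depth alone, a count of 0 allows a level of up to 3 counts in the library's total, 0.0717 CPM at 41844825 counts and 0.306 CPM at 9796799. Transcripts lost before sequencing are not covered by this limit. Groups were taken from the firing type in the labels. Each sample is 1 cell and no animal, donor or culture is named, so each type was treated as 1 sample: no model was fitted across genes, and no p-value, standard error or count of changed genes was computed from neurons. Differences were described by the size of the type 2 minus type 1 difference of mean log2(CPM + 1), by values per neuron, and by the number of neurons at 10 CPM or more with at least 3 counts. Shares of neurons have exact (Clopper-Pearson) binomial 95% intervals and summed levels exact Poisson 95% intervals. All pairs of libraries differed far beyond sampling noise (lowest chi-square per degree of freedom 619 over 45 pairs), so no library was a copy of another.

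Genes were named by a rule set before the data were examined; 5 genes are not reported here. It took the 10 largest differences in each direction among genes detected in at least 4 of 5 neurons of the higher type, leaving out unnamed, predicted, mitochondrial, ribosomal protein, haemoglobin and pseudogene entries. It took from each of 25 fixed gene lists the 2 members with the largest difference among those detected in at least 3 neurons of a type, then 17 genes of transmitters, peptides and hindbrain identity, and the 5 genes with the highest median CPM. The lists were leptin receptor signalling, glutamatergic, GABA and glycine, monoamine and acetylcholine, neuropeptides, metabolic and peptide receptors, hindbrain transcription factors, 5 groups of ion channels, 2 groups of transmitter receptors, pan-neuronal genes, 4 other cell types, immediate early and stress genes, nuclear-retained RNAs, oxidative phosphorylation, cytosolic ribosomal proteins, synaptic vesicle release and sex-linked genes. For each, the median difference over members with a mean of at least 1 CPM was placed among the medians of 10000 random lists of the same size matched in 20 bins of mean level. A list was said to stand apart below percentile 2.5 or above 97.5, as a description of these libraries.

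The alternatives were pseudocounts of 10 and 0.1, TMM-scaled library sizes, totals without the 50 most abundant genes or without mitochondrial genes, thinning to the smallest library, ratios of mean CPM and of summed counts, medians over neurons, equal weight for each first number of the neuron names, neurons with first number 9 alone, other filters, and leaving out each neuron in turn. Restricting to libraries over or under 20000000 counts and leaving out 6-2, 9-2 and 9-4 were chosen after seeing the data. In tests chosen after seeing the data, 20 genes were also chosen by the same rule in some neurons and measured only in others. The procedure was tested on simulated data: on counts drawn for the 14607 genes at the real library sizes of the type 2 minus type 1 comparison, 50 genes set 4-fold higher gave a median difference of 1.918 and 50 set 2-fold higher gave 0.756. Of simulated unchanged lists, 7.0% fell outside the percentile limits. The simulated genes varied independently of each other around a common mean level, unlike real genes that were high in some neurons and near absent in others. The 7.0% therefore does not cover lists whose members vary together. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, R 4.3.3 and edgeR 4.0.16 (for the TMM factors only) were used.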

Results

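RNA was aspirated through a patch pipette from single neurons of the nucleus of the solitary tract, a brainstem nucleus that receives visceral sensory input. The neurons came from acute slices of 3-month-old C57BL/6 mice in which cells expressing the leptin receptor (Lepr) carry a yellow fluorescent protein reporter. Each library held the cytoplasmic and nuclear RNA of 1 neuron. The labels divide the 10 neurons by firing property into 5 of type 1 (numbered 1-1, 1-2, 4-3, 8-2 and 9-1) and 5 of type 2 (6-2, 10-1, 10-3, 9-2 and 9-4), without saying what the numbers or the firing properties are. The question is which genes differ in level between the firing types of leptin receptor neurons. Gene counts ranged from 9796799 in 4-3 to 41844825 in 8-2. Totals were under 20000000 in 1-1, 1-2, 4-3 and 6-2 and above it in the other 6 neurons, so 3 of 4 libraries in the lower depth set and 2 of 6 in the higher were type 1. The labels name no animal or slice, so each firing type counts as 1 sample: values are given per neuron or as mean ± SD between the 5 neurons of a type, which is spread between cells only, and no test between types was made. Levels are in CPM (counts scaled to the same library total), a gene was taken as detected at 10 CPM or more and at least 3 counts, and differences are type 2 minus type 1 means of log2(CPM + 1). Binomial and Poisson intervals cover counting error only, since amplified reads are not independent molecules.

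Lepr itself (ENSMUSG00000057722, GRCm38 chromosome 4, 101717404 to 101815352, plus strand), the gene whose promoter activity marked the neurons, was low and uneven in both types. It was detected in 2 of 5 type 1 neurons (40.0%, exact binomial 95% interval 5.27 to 85.3%), at 122 CPM in 1-1 and 59.8 CPM in 4-3, and in 4 of 5 type 2 neurons (80.0%, 28.4 to 99.5%), at 29.4 to 50.7 CPM. The other 4 neurons had 0.89 to 5.09 CPM, and all 10 had at least 1 count. Mean Lepr was 38.1 ± 52.9 CPM in type 1 and 29.4 ± 18.0 CPM in type 2 (SD, n = 5 neurons each), while the log2 difference was 0.65, so its sign depends on whether CPM or log values are averaged. At a level of 50 CPM, Lepr was detected in 2 type 1 neurons and 1 type 2 neuron. Of 14 measured genes of the leptin receptor signalling list, 6 had a higher mean log2 level in type 2 and 8 in type 1 (median difference -0.17, percentile 20.69 of 10000 matched random lists). Pik3r1, a regulatory subunit of phosphoinositide 3-kinase, was detected in 4 type 1 neurons and 0 type 2 neurons (66.6 ± 87.3 against 0.54 ± 0.669 CPM). Leprotl1, a relative of the transcript made upstream of Lepr, was detected in 2 and 5 (46.8 ± 60.1 against 147 ± 102 CPM).

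Type 2 neurons were marked by Gcg, the proglucagon gene from which glucagon-like peptides are made. Gcg (ENSMUSG00000000394, chromosome 2, 62474530 to 62483650, minus strand) reached 3556 to 17679.8 CPM in every type 2 neuron (7658 ± 5851 CPM) and 0 to 14.1 CPM in type 1 (5.46 ± 7.45 CPM), a log2 difference of 11.06. Summed over neurons it was 7715 CPM in type 2 (exact Poisson 95% interval 7701 to 7729) and 8.97 CPM in type 1 (8.42 to 9.54). The type 1 Gcg reads lay in 8-2 and 9-1, both in the higher depth set; the 3 type 1 libraries of the lower depth set held at most 0.0722 CPM. Prlr, the prolactin receptor (ENSMUSG00000005268, chromosome 15, 10177238 to 10349180, plus strand), was at 331 ± 206 CPM in type 2 and 0.274 ± 0.395 CPM in type 1 (difference 7.87). Crhbp, which encodes the binding protein of corticotropin-releasing hormone, was at 494 ± 344 against 13.4 ± 28.6 CPM. Stxbp2, a syntaxin-binding protein, Mcub, a subunit of the mitochondrial calcium uniporter complex, Sh3bgrl2, the secreted guidance factor Sema3c and the Integrator subunit Ints10 were also among the 10 largest positive differences, with values of 6.70 to 7.55, each below 1 CPM in every type 1 neuron. In the 3 genes Stxbp2, Sema3c and Ints10 the type 2 means were 263 ± 208, 195 ± 196 and 119 ± 52.6 CPM.

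Type 1 neurons were marked by Gal, the gene of the neuropeptide galanin. Gal (ENSMUSG00000024907, chromosome 19, 3409915 to 3414544, minus strand) was at 1859 to 5124 CPM in type 1 (3334 ± 1294 CPM) and 0 to 149 CPM in type 2 (37.7 ± 63.9 CPM), a difference of -8.49. Its summed level was 3918 CPM in type 1 (Poisson interval 3906 to 3929.7) and 39.3 CPM in type 2 (38.3 to 40.3), with the type 2 signal mainly in 9-4 (149 CPM) and 9-2 (32.6 CPM). Fibcd1, a membrane receptor that binds acetylated compounds, was at 247 ± 188 against 0.293 ± 0.395 CPM, and Cntn5, a contactin adhesion molecule, at 187 ± 69.8 against 0.177 ± 0.178 CPM. Omp, first known as a marker of olfactory sensory neurons, was at 191 ± 111 against 0.179 ± 0.244 CPM. The homeobox gene Irx2 was at 239 ± 237 against 0.171 ± 0.227 CPM. Grik1, a kainate receptor subunit, was at 234 to 434 CPM in 4 type 1 neurons but at 0.167 CPM in 8-2. Crtac1, Ttc39c, the Wnt pathway modulator Dkk2 and the receptor phosphatase Ptprz1 completed the 10 largest negative differences, with values of -7.07 to -6.41, type 1 means of 117 to 225 CPM and type 2 means below 1 CPM.

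In all 10 genes higher in type 2 every type 2 neuron exceeded every type 1 neuron, and in 9 of the 10 higher in type 1 the reverse held, Grik1 being the exception. Of the 252 ways to order 5 neurons against 5, 2 (0.794%) separate the ranges of a gene. That share takes neurons as independent, while some share a first number and the types are uneven over the depth sets. These 20 genes were also picked for the size of their difference. The median size of the 20 differences was 7.18, against 7.04 within the higher depth set and 7.28 within the lower, and all 20 kept their direction in both, which choosing them over these same neurons favours. Among the 3 neurons whose first number is 9, the only first number found in both types, the median size was 7.48.

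**Figure D1:**
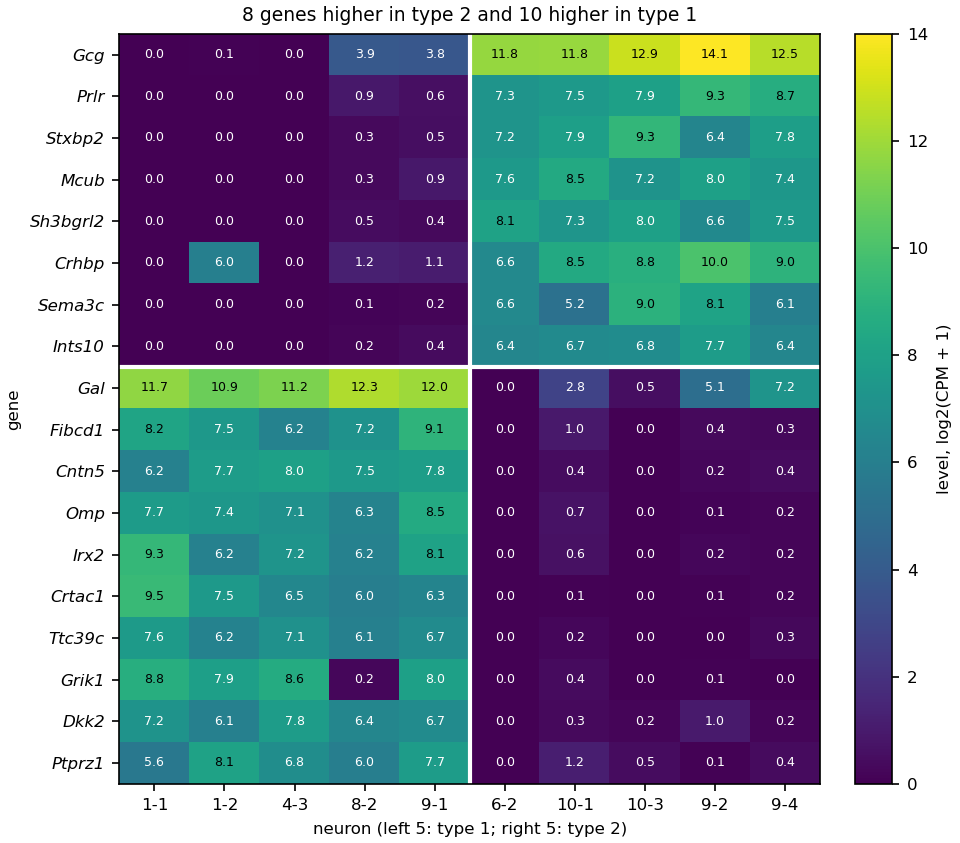
Levels of 18 of the 20 genes with the largest differences, as log2(CPM + 1), in each of the 10 neurons, with the 8 genes higher in type 2 above the white line and the 10 higher in type 1 below it. Gcg was at 3556 CPM or more in all 5 type 2 neurons and Gal at 1859 CPM or more in all 5 type 1 neurons, while Grik1 was at 0.167 CPM in the type 1 neuron 8-2.

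The glutamate transporter gene Slc17a6, which marks excitatory neurons, was detected in all 10 neurons, at 412 ± 209 CPM in type 1 and 221 ± 104 CPM in type 2 (difference -0.85). In the glutamatergic list 4 of 5 measured genes had the higher mean in type 1 (median -1.03, percentile 1.18; -1.61 in the higher and -0.65 in the lower depth set). Grin3a, an NMDA receptor subunit, was the furthest apart (234 ± 166 against 60.2 ± 82.2 CPM, detected in 5 and 2 neurons). Gad2, which encodes a GABA-synthesising enzyme, was detected in 2 type 1 neurons (481 CPM in 1-1 and 333 CPM in 4-3) and in all 5 type 2 neurons (224 to 756 CPM). The vesicular GABA transporter gene Slc32a1 was detected only in 4-3, at 11.9 CPM, and Gad1 was detected only in 6-2, at 31.5 CPM. Over the 6 measured GABA and glycine genes the median difference was -0.04 and the mean 0.86 (percentile of the median 37.06). Slc6a5, the neuronal glycine transporter, was detected only in 9-1, at 84.0 CPM. The glutamatergic list fell inside the middle 95% of random lists without 1-1 (percentile 4.64), 8-2 (3.14) or 10-1 (5.55), in neurons numbered 9 (24.07) and in the lower depth set (5.11).

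Catecholamine genes were found in differing sets of neurons. Th, the first enzyme of catecholamine synthesis, was at 261 CPM in 1-2 and at most 0.082 CPM elsewhere, and Dbh, which makes noradrenaline, was at 117 CPM in 9-1 and 546 CPM in 9-4 and below 1 CPM elsewhere. Ddc, the decarboxylase shared by monoamine pathways, was detected in 3 type 1 neurons and all 5 type 2 neurons (59.2 ± 70.5 against 384 ± 293 CPM), and Gch1, needed for the cofactor of Th, in 1 and 3. Chat was undetected in every neuron, with 8.81 CPM in 9-4 as its highest level. The 8 measured genes of the monoamine and acetylcholine list had a median difference of 1.23 (percentile 93.75). Of the other peptides, Penk, the proenkephalin gene, was at 3223 to 10726 CPM in type 2 and ranged from 3.57 CPM in 4-3 to 4093 CPM in 8-2 in type 1 (difference 5.74). Pomc was detected at 11.1 to 31.5 CPM in all 5 type 2 neurons and at 32.0 CPM in 1-1 alone among type 1 neurons. Cck, the cholecystokinin gene, was detected in 10-3, 9-2 and 9-4 (756, 63.7 and 233 CPM) and in 0 of 5 type 1 neurons (exact binomial interval 0.0 to 52.2%). Over 25 measured neuropeptide and peptide-processing genes 12 were higher in type 2 and 13 in type 1 (median -0.08, percentile 17.98).

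**Figure D2:**
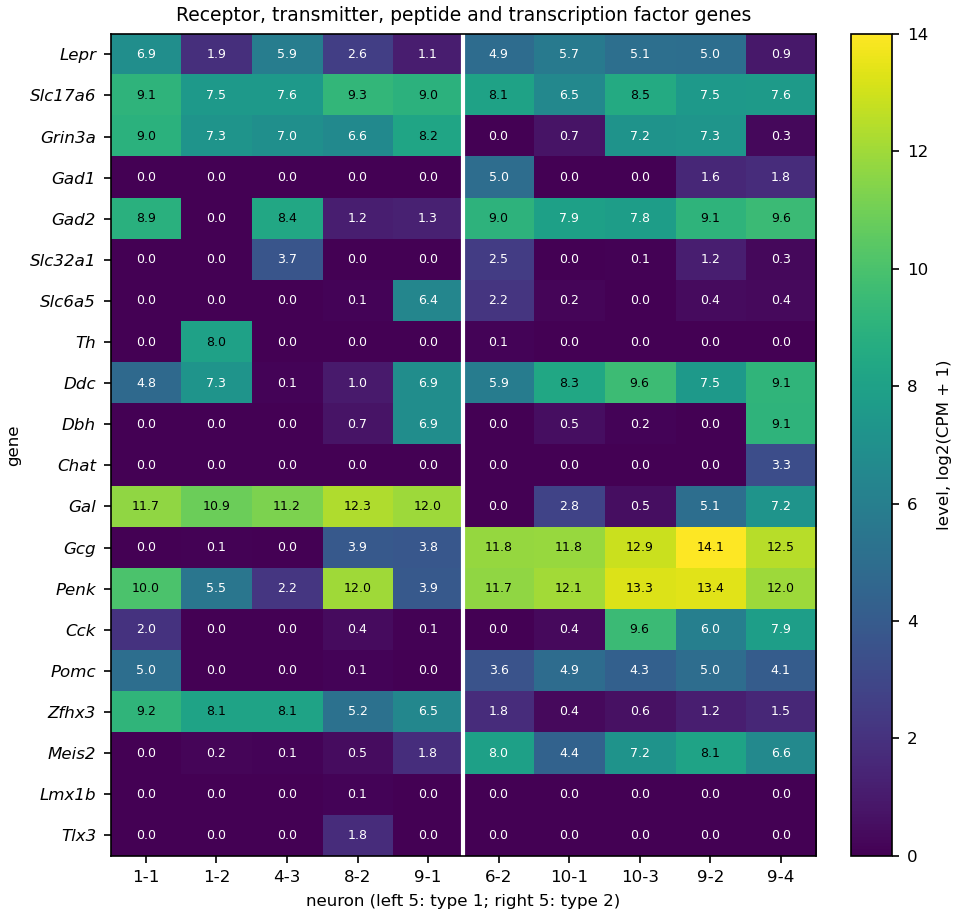
Levels of Lepr and of transmitter, peptide and transcription factor genes, as log2(CPM + 1), in each of the 10 neurons. Slc17a6 was detected in all 10, Gcg and Penk were high in all 5 type 2 neurons, Gal and Zfhx3 were higher in all 5 type 1 neurons than in any type 2 neuron, and Th was detected only in 1-2.

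Transcription factors of hindbrain neurons differed in both directions. Zfhx3, a zinc finger homeobox gene, was at 251 ± 211 against 1.28 ± 0.914 CPM (difference -6.33), and Meis2, a homeobox cofactor, was opposite, at 0.634 ± 1.06 against 157 ± 108 CPM (difference 6.32). Lmx1b and Tlx3, which mark dorsal hindbrain excitatory neurons, were undetected in all 10 neurons, with highest levels of 0.0956 and 2.49 CPM. In the list as a whole 20 of 27 measured genes were higher in type 1 (median -0.80, percentile 0.46; -0.69 in the higher and -0.88 in the lower depth set). That percentile was 2.95 in the higher depth set, 3.69 without 1-1 and 4.37 without 9-2, where the median was -0.48.

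Receptor genes were mostly sparse. In the metabolic and peptide receptor list 18 of 22 measured genes had the higher mean in type 2 (median 1.07, percentile 98.71), and only 5 of the 22 were detected in 3 or more neurons of a type. Besides Prlr, the oestrogen receptor gene Esr1 was detected in 10-1, 10-3 and 9-2 (63.3 to 96.4 CPM) and was at most 0.159 CPM in type 1. Calcr and Glp1r, the calcitonin and glucagon-like peptide receptors, had 0 counts in all 10 neurons. By sequencing depth alone that allows at most 0.0717 CPM in the deepest library and 0.306 CPM in the shallowest. Single libraries can also lack a gene that is high in others, as with Ndufv1, at 0 CPM in 4-3 and 170.4 to 341 CPM in the other type 1 neurons. Absence of Calcr and Glp1r from these neurons is therefore not shown. With medians over neurons in place of means the receptor list was at 0.04 (percentile 76.05). Its median was 1.23 in the higher and 0.0 in the lower depth set, 0.73 without 9-2 (percentile 91.27) and 0.98 without 9-4 (96.20). In the 18 GABA and glycine receptor genes 11 were higher in type 2 (median 0.15, percentile 43.2), with Gabrb2 detected in 0 type 1 and 4 type 2 neurons (0.051 ± 0.0734 against 32.0 ± 26.8 CPM). Gria3, an AMPA receptor subunit, was at 1.67 ± 3.18 against 129 ± 99.9 CPM, opposite in direction to Grik1, within an ionotropic glutamate receptor list whose median was 0.71 (percentile 76.15).

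Ion channel genes bear on firing and showed differences in single members. Among 20 measured calcium channel genes 14 were higher in type 1 (median -0.91, percentile 0.47). Their beta subunit gene Cacnb3 was at 252 ± 167 against 48.8 ± 44.0 CPM, and Cacng3, an AMPA receptor auxiliary subunit in the calcium channel gamma family, at 54.4, 44.1 and 111 CPM in 6-2, 10-1 and 9-4 and below 1 CPM elsewhere. The list's median was 0.17 in the higher depth set and -1.12 in the lower, and without 1-1, 1-2 or 10-1 it was -0.48, -0.51 and -0.51 (percentiles 8.81, 4.42 and 4.41). Among neurons numbered 9 it was -0.08 (10.44) and with first numbers weighted equally -0.42 (6.20), and it lay inside the middle 95% of random lists in 10 of 26 alternatives. Kcnip1, which modulates A-type potassium channels, was detected in 4 type 1 neurons and only 9-4 of type 2 (137 ± 113 against 22.4 ± 49.6 CPM), and Kcns3, a modulatory subunit, in 0 and 3 (0.0319 ± 0.0712 against 49.1 ± 61.9 CPM). Kcnk2, a background potassium channel, was at 100.4 ± 94.9 against 20.7 ± 24.7 CPM, and the calcium-activated channel Kcnma1 at 27.5 ± 37.1 against 45.3 ± 34.1 CPM. Pkd2, a TRP family channel, was detected in 3 type 1 neurons and 0 of type 2. Scn9a and Scn1a, the sodium channels furthest apart, had differences of -1.76 and 1.72. The medians of the voltage-gated potassium (0.28, percentile 60.28), other potassium (0.17, 43.43), sodium (0.17, 42.76) and HCN and TRP channel lists (0.86, 84.65) all lay inside the middle 95% of random lists.

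**Figure D3:**
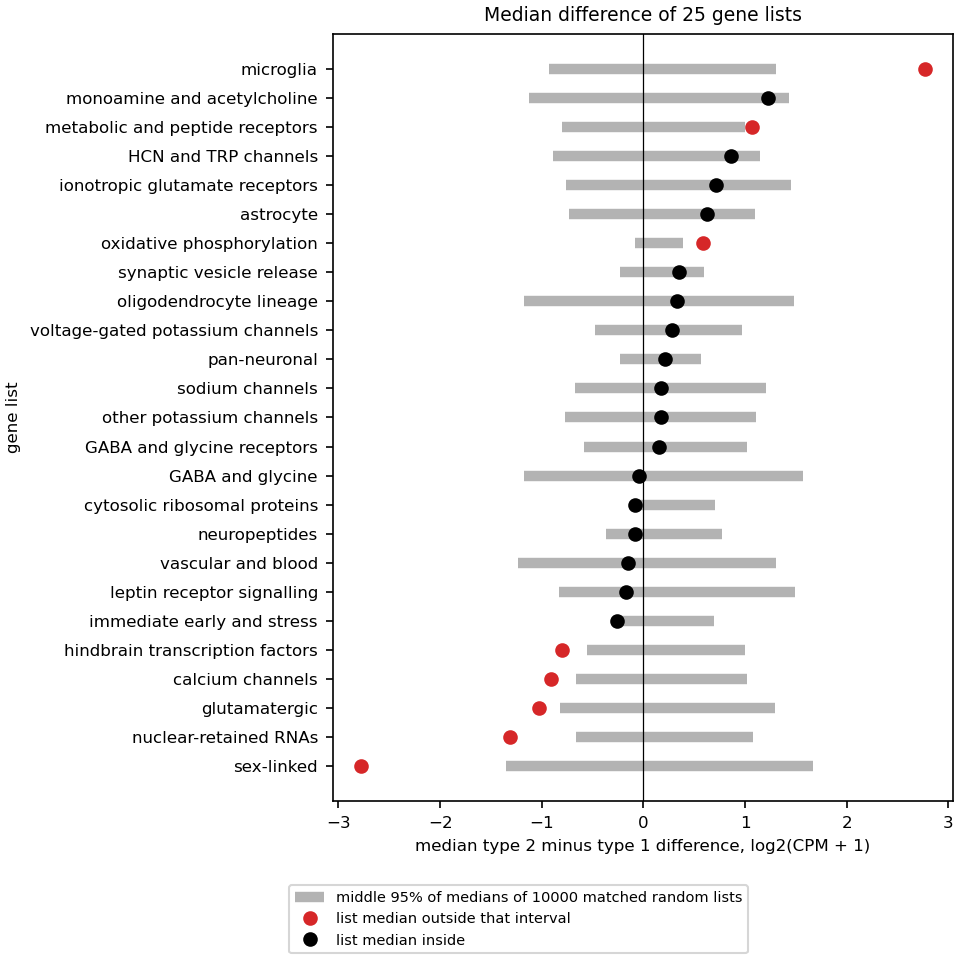
Median type 2 minus type 1 difference of each of the 25 gene lists (points) and the middle 95% of the medians of 10000 random lists matched on size and mean level (grey bars), on the log2(CPM + 1) scale. The 8 red points lie outside their bars, from the sex-linked list at -2.78 to the microglia list at 2.77.

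Genes of mitochondrial oxidative phosphorylation were higher in type 2: 65 of 71 had the higher mean there (median 0.59, percentile 99.98; 0.59 in the higher and 1.02 in the lower depth set). Ndufa2 was at 122 ± 68.8 against 324 ± 105 CPM and Ndufv1 at 206 ± 130.1 against 404 ± 122 CPM. The median difference of all 9212 genes with a mean of at least 10 CPM was 0.24, and 0.409 with TMM scaling, under which the oxidative phosphorylation list was at 0.81. For all these genes the median was 0.0 in the higher and 0.635 in the lower depth set, where 6-2 is the only type 2 neuron. Microglial transcripts moved with the same type: all 14 microglial genes had the higher mean in type 2 (median 2.77, percentile 100), and 13 of 14 were detected in 6-2, 13 in 9-4 and 7 in 9-2, against 5 in 1-2 and 0 to 2 in the other 6 neurons. Tyrobp was at 112 to 124 CPM and Csf1r at 56.9 to 79.5 CPM in those 3 type 2 neurons. Without 6-2, 9-2 and 9-4, an alternative chosen after the values were seen, 10-1 and 10-3 were the only type 2 neurons left. The type 1 neuron 1-2, with 5 microglial genes detected, was kept. The medians were then 0.36 for oxidative phosphorylation (percentile 88.94), 0.01 for the peptide receptors (82.46), -0.57 for hindbrain transcription factors (14.25) and -0.83 for calcium channels (9.97). The microglia median of 0.01 was largely set by this choice of neurons, and the other values cannot be tied to microglial RNA. The 20 largest differences had a median size of 7.08.

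Nuclear-retained RNAs were lower in type 2 in 10 of 10 measured members (median -1.31, percentile 0.06; -0.81 in the higher and -0.63 in the lower depth set, percentiles 4.26 and 3.59). Only 6 of the 10 were detected in 3 or more neurons of a type. The 10 include Xist, also in the sex-linked list, at 77.4 CPM in 9-1 and at most 1.84 CPM elsewhere. Malat1 was at 13657 ± 9709 CPM in type 1 and 4051 ± 3100.3 CPM in type 2, with 1783 CPM in 8-2 and 8269.9 CPM in 6-2, so the ranges overlapped. Markers of other cell types gave list medians of 0.63 for astrocytes (percentile 85.55), 0.33 for the oligodendrocyte lineage (57.51) and -0.15 for vascular and blood cells (37.72). Only 7 of 16, 6 of 17 and 4 of 20 genes of these lists were measured. In the higher and lower depth sets the medians were 1.23 and 1.93 for astrocytes, -1.61 and -0.04 for the oligodendrocyte lineage, and 0.48 and -0.34 for vascular and blood cells. Aldoc and Cst3, abundant in astrocytes, were at 394 ± 228 against 1296 ± 422 CPM and 484 ± 273 against 1715 ± 1163 CPM, with Cst3 highest in 6-2 and 9-4, the neurons with most microglial genes. Pan-neuronal genes had a median of 0.21 (percentile 50.66), with the neurofilament gene Nefl at 1106 ± 443 against 136 ± 126 CPM and Rbfox3 at 77.3 ± 40.1 against 15.4 ± 23.2 CPM. Synaptic vesicle release genes had a median of 0.35 (percentile 75.9): Sv2c was at 1.98 ± 4.2 against 78.2 ± 54.6 CPM and Rims2 at 134 ± 99.7 against 25.3 ± 23.0 CPM. Cytosolic ribosomal protein genes had a median of -0.08 (percentile 2.94), and 0.57 and 1.05 in the higher and lower depth sets.

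**Figure D4:**
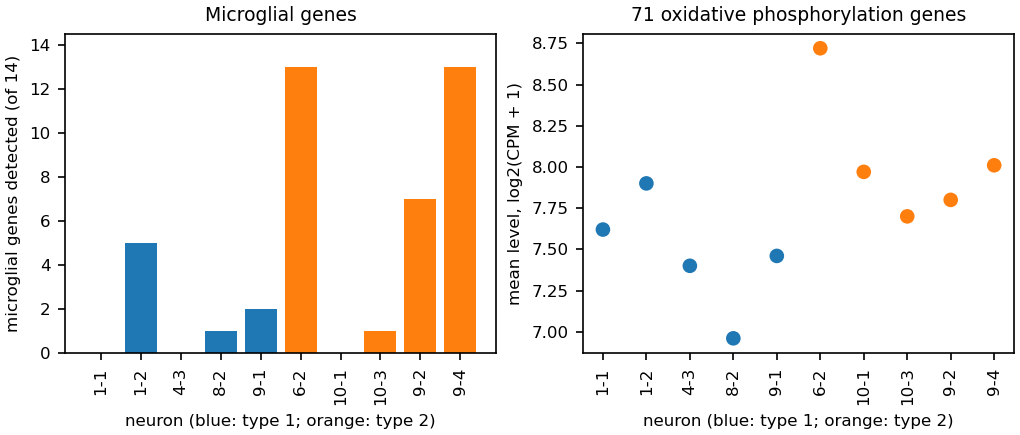
Left, number of the 14 microglial genes detected in each neuron (bars); right, mean level of the 71 oxidative phosphorylation genes in each neuron (points), as log2(CPM + 1) on an axis that does not start at 0. Neurons 6-2 and 9-4 each had 13 microglial genes, and 6-2 had the highest oxidative phosphorylation level, 8.72.

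Y-linked genes reached the detection level in type 1 neurons only. Ddx3y was at 102, 126 and 229.8 CPM and Eif2s3y at 174, 355 and 74.2 CPM in 1-1, 1-2 and 8-2, and both were below 2 CPM in the other 7 neurons. Xist, expressed from the inactive X chromosome of females, was at 77.4 CPM in 9-1, 1.84 CPM in 4-3 and at most 0.12 CPM elsewhere. The sex-linked list's median of -2.78 (percentile 0.02) rests on Ddx3y in these 3 neurons and on Xist in 9-1, and it was -3.24 in the higher and -3.02 in the lower depth set. The labels give no sex.

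Type 2 neurons resembled each other more than they resembled type 1 neurons, and type 1 neurons did not. Over 9212 genes the mean Spearman correlation, across genes, which are not independent replicates, was 0.554 among type 2 neurons, 0.427 among type 1 neurons and 0.44 between types. The mean within types (0.49) exceeded that between types by 0.0503, and 8 of 10 neurons were nearer on average to their own type, 3 of them type 1 neurons with margins of only 0.00119 to 0.017, the exceptions being 8-2 and 9-1, the type 1 neurons of the higher depth set. Within that depth set the excess was 0.0567. There 8-2 and 9-1 correlated at 0.533 with each other and at 0.417 to 0.576 with the type 2 neurons. With the type 1 neurons of the lower depth set they correlated at 0.389 to 0.454. Without 10-3, 9-2 or 8-2 the excess was 0.0288, 0.0309 and 0.0768. Genes with at least 1 count numbered 6879 to 10859 in type 1 (median 8004) and 9680 to 10953 in type 2 (median 10184). After thinning every library to 9796799 counts the medians were 7887 and 9598. The difference in medians, 2180 genes, was 793 without 1-1 or 4-3, 1014.5 without 1-2, and -399.5 within the higher depth set, so it did not hold there. Of the 5 most abundant genes, Malat1 had the lower and Penk the higher mean in type 2, as given above. Zwint was at 6171 ± 1321 and 8068 ± 1389 CPM, Nap1l5 at 7173 ± 966 and 6058 ± 885 CPM, and Gnas, the stimulatory G protein subunit, at 3247 ± 197 and 6138 ± 1942 CPM, with every type 2 neuron above every type 1 neuron.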

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

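In 94 groups of 5 neurons (library measures, list levels and 18 of the 20 genes with the largest differences, within each type), 12 held a neuron whose gap to its nearest neighbour exceeded 0.71 of the group's range. For independent and normally distributed values chance gives about 1 in 20, or 4.7. These groups share neurons and some levels lie below 1 CPM, so 12 cannot be read as an excess over chance. All tests of explanations below were chosen after the results were seen.

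In type 1, 8-2 had a share of 9.78% of counts in the 50 most abundant genes (group median 11.6%), a mean leptin receptor signalling level of 5.6 (4.03) and a Grik1 level of 0.22 (7.96), all levels as log2(CPM + 1). Neuron 1-2 had a mean hindbrain transcription factor level of 3.39 (4.18) and a Crhbp level of 6.04 (1.08), and 1-1 had a Cntn5 level of 6.15 (7.72). The pan-neuronal level was 8.79 in 9-1 (8.24), and the vascular and blood level was 4.01 in 4-3 (2.91). In type 2, 9-2 had a level of 3.58 for the other potassium channels (2.11) and an Ints10 level of 7.73 (6.68). The cytosolic ribosomal protein level was 7.51 in 6-2 (4.65), the only type 2 neuron of the lower depth set. It was 6.13 to 6.75 in the type 1 neurons of that set and 3.86 to 4.79 in all neurons of the higher set. The Grik1 level was 0.42 in 10-1 (0.0452), which is below 1 CPM.

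Gcg reads in the type 1 neurons 8-2 and 9-1 amounted to 590 and 412 counts. Among 66 other genes below 0.5 CPM in 1-1, 1-2 and 4-3 and at 20 CPM or more in the 4 type 2 libraries of the higher depth set, 26 in 8-2 had counts between 0.0109 and 0.476% of those in the 4 libraries and the other 40 had at least 1.57%; in 9-1 the ranges were 0.011 to 0.465% (44 genes) and at least 3.92% (22 genes). Gcg lay within the lower range in both, at 0.053% and 0.037%, which is what reads carried over between libraries of 1 depth set may give. The 2 ranges were split at 1%. Gcg was so high in type 2 that true low expression would also fall under 1%, so this placement cannot tell it from carry-over. The 3 other type 1 libraries held at most 0.0722 CPM. Single libraries can lack a gene that is present in others, so these values cannot decide on low Gcg expression shared by type 1 neurons. True low expression in 8-2 and 9-1 alone stays open; Gal counts, as a share of those in 8-2 and 9-1, were 0.0748, 0.00442, 0.274 and 1.38% in the type 2 neurons 10-1, 10-3, 9-2 and 9-4, the last above the 1% line.

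The separation of the types by the genes with the largest differences was examined with genes chosen in some neurons and measured in others, because neurons that choose the genes favour the outcome; scores are the median level of 10 chosen type 1 genes minus that of 10 chosen type 2 genes. Among neurons of first number 9, genes chosen in the other 7 neurons had a median difference of 6.36 (18 of 20 in the chosen direction), but 9-1 is the only type 1 neuron there, so what that number marks cannot be told apart. For sex of the animals, genes chosen without 4-3, 9-1, 9-2 and 9-4 had 4.9 between these type 1 neurons with little Y-linked signal and these type 2 neurons (score gap 6.21, larger SD of a type 3.18). That cannot decide on sex, because the reads do not show the sex of 9-2 and 9-4 (Xist at most 0.0351 CPM, summed Y-linked genes at most 1.54 CPM). The same holds for 4-3 (1.84 and 0.306 CPM), and only 9-1 had clear Xist signal (77.4 CPM). For the library depth set, both sets hold both types. The 20 differences had median sizes of 7.04 and 7.28 within them, which choosing the genes in these same neurons favours. Genes chosen in the higher set had 7.18 in the lower (score gap 14.3, SD 0.29), but 6-2 is the only type 2 neuron there. Those chosen in the lower had 3.88 in the higher, with 17 of 20 in the chosen direction. Their score gap of 2.62 was below the SD of 2.74, the bound first set for this test and dropped after it was missed. The types thus differed in the chosen direction within both sets, which the depth set alone would not give. The depth set as the whole cause is still left open. The gap in the higher set was below the spread, and the lower set rests on 6-2 for type 2. An animal or slice effect was not tested because none is labelled, and a difference of the firing types themselves stays open.

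Microglial transcripts in some neurons were found together: the number of detected microglial genes ranged over neurons from 0 to 13, a spread larger than in 100% of 10000 matched random lists, whose largest was 12. RNA of a neighbouring cell taken up with the neuron may give such a pattern, but the comparison restates the joint detection that prompted it and adds no support. The members with high values, chosen after those were seen, included Ctss (312 CPM in 6-2, 219 CPM in 9-4) and C1qb (315 and 285 CPM). Carry-over of reads is argued against, since the summed microglial level in 9-4 was 227% of that in the other 5 libraries of the higher depth set together. Each neuron was visualised before its contents were drawn, and no biological explanation was tested. With 3 of 5 type 2 neurons and 1 of 5 type 1 neurons holding 5 or more of these genes, the cell source of Cst3 and oxidative phosphorylation transcripts, highest in 6-2 and 9-4, stays open; the oxidative phosphorylation level was 8.01 in 9-4 and 7.97 in 10-1, which had 0 microglial genes.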

How the results depend on the processing

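The 20 largest differences kept their direction in every alternative run, as choosing them by size in the same neurons favours, with median sizes between 4.2 (pseudocount 10) and 9.56 (pseudocount 0.1) against 7.18. The lists also depended on the setting, and the causes were not tested. The receptor list was 0.04 with medians over neurons (percentile 76.05), 0.37 with pseudocount 10 (95.97) and 0.9 with first numbers weighted equally (94.09). Neurons of first number 9 alone gave 2.44 for it, -0.08 for calcium channels (10.44) and -0.44 for the sex-linked list, which was -5.07 with the ratio of mean CPM, -5.28 with the ratio of summed counts and -1.19 with no filter. In alternatives chosen after seeing the data, libraries of the higher depth set reversed the calcium channel list (0.17) and gave -399.5 for the difference in genes with at least 1 count. Libraries of the lower depth set gave 5.66 for microglia and 1.02 for oxidative phosphorylation, with a median of 0.635 for all genes with a mean of at least 10 CPM. Leaving out 6-2, 9-2 and 9-4, with 10-1 and 10-3 as the type 2 neurons left, gave 0.01 for microglia and -1.8 for the glutamatergic list. The difference in genes with at least 1 count ranged from 793 to 2415 with 1 neuron left out. For genes at 1 CPM or more it was 1269, and at 10 CPM or more 945. The excess correlation within types was 0.0846 for genes of at least 100 CPM and 0.0288 to 0.0768 with 1 neuron left out. With at least 1 count Lepr was found in 5 and 5 neurons, and at 50 CPM in 1 type 2 neuron. With 1 neuron left out the list medians ranged from -1.22 to -0.61 (glutamatergic), 0.73 to 1.32 (receptors), -1.0 to -0.48 (hindbrain transcription factors), -1.06 to -0.48 (calcium channels), 1.8 to 3.42 (microglia), -1.46 to -0.99 (nuclear-retained RNAs), 0.44 to 0.69 (oxidative phosphorylation) and -3.33 to -2.55 (sex-linked). Leaving out 6-2 or 9-4 gave 1.8 and 1.84 for microglia. The 20 largest differences then ranged in median size from 6.98 to 7.44. Oxidative phosphorylation, microglia and sex-linked genes stood apart in 25 of 26 alternatives, nuclear-retained RNAs in 24, hindbrain transcription factors in 22, glutamatergic genes in 21, receptors in 19 and calcium channels in 16. Of the other values, named genes included, 2252 moved by less than the spread between neurons and 139 by more. The total without mitochondrial genes changed nothing because those genes had 0 counts. No paired analysis was possible because only the first number 9 occurs in both types, and its meaning is not given in the sources used here. Depth limits values below about 0.3 CPM in the shallowest library, and in the 6 deeper libraries a median of 3089 genes lay between 0 and 1 CPM, against 944 in the other 4, so levels below 1 CPM were not read as expression. After thinning to the same total, the median number of genes with at least 1 count was 9560 in the 6 and 7724 in the 4. Depth alone does not give that difference, and no batch is labelled.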

Other observations

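Immediate early and stress genes were detected in both types, with a list median of -0.26 (percentile 3.27), just inside the range of random lists. Atf3, induced by cell injury and stress, was at 48.6 to 3224 CPM in all 5 type 1 neurons and was detected in 1 type 2 neuron, 9-4, at 68.3 CPM. Egr4 went the other way, at 277, 727, 824 and 81.1 CPM in 6-2, 10-1, 10-3 and 9-4 and, among type 1 neurons, at 398 CPM in 1-1 alone. Fos, chosen after its values were seen, was at 513 CPM or more in every neuron, highest in 9-1 at 8343 CPM, the neuron with the highest Atf3. Firing and slice preparation precede the aspiration of each cell, and their part in these levels was not tested.

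Some receptors and peptides chosen after their values were seen are given here by neuron. Mc4r, the melanocortin receptor of appetite control, was at 142 CPM in 9-2 and 191 CPM in 9-4 and below 1 CPM in the other 8 neurons. Oprm1, the mu opioid receptor, was at 138 CPM in 9-2 and 26.5 CPM in 10-3. Bdnf was at 174, 178 and 71.8 CPM in the type 1 neurons 1-1, 1-2 and 9-1 and at 33.0 CPM in the type 2 neuron 9-4. Adcyap1, which encodes a peptide of excitatory neurons, was detected in all 10 neurons, at 471 ± 261 CPM in type 1 and 448 ± 334 CPM in type 2 (SD, n = 5 neurons each).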
